A study of Dietzia sp. DQ12-45-1b with 9 samples.

How the data were processed

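The data are RNA-seq gene expression values from 9 samples of Dietzia sp. DQ12-45-1b, titled as 3 replicates each on octacosane, hexadecane and glucose. Per the labels' protocols, a preculture of 36 h was used to start 50 mL cultures at an optical density of 0.1, these were grown at 30 °C to mid-log phase, RNA was extracted with TRIzol and treated with DNase I, and libraries were sequenced on an Illumina instrument. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

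The deposited values are FPKM, fragments scaled by gene length and by the mapped total of the library, 1 file per sample, per the file headers. The submitters' processing notes name HISAT2; its version, the genome build and the counting tool are not given in the sources used here. FPKM divides by gene length and by the library's mapped total, so a few very abundant transcripts lower the values of the others, and the number of reads behind a value cannot be recovered; few genes had low values and no steps of single reads could be resolved. No interval for counting error is given for that reason. Gene identity comes from the locus tags and product names in the files, in which hyphens were missing; names are printed here with hyphens restored. No genome was used, so genes have no coordinates here, and neighbours are neighbours in locus tag order. Near-identical gene copies could share fragments, and strand handling is not given in the sources used here.

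The files of octacosane replicates 1 and 3 held the same value for each gene and were counted once. The file of octacosane replicate 2 carried the name of octacosane replicate 1 inside, with different values, and kept its group. The file titled glucose replicate 3 carried the name of an octacosane sample inside. Because 2 labels of the same file disagree on its group, it was left out of the main comparisons, for its name and not for its values. The design fixed before the data were examined had all 9 libraries, so this is a departure from it; the fits with that file as glucose and as octacosane are given as alternatives added after seeing the data. The libraries compared were therefore 2 octacosane, 3 hexadecane and 2 glucose, with 4 residual degrees of freedom.

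Values were transformed to log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3, in 1 model for all 3 groups, with an intensity trend and robust moderation. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes had to reach 1 FPKM in at least 3 libraries, a filter that removed 0 of 3348 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1; intervals are 95% intervals of the log2 fold change. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

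Before the data were examined, 24 gene lists were fixed as patterns in product names, along with the tests, the alternatives and the rule for named genes. One list, of structural RNA, had no member and 22 lists had at least 5 members and were tested in 3 comparisons with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes. With the correlation estimated from the data, camera passed 0 of the 66 tests, and 2 had an unadjusted p under 0.05. Some members match a list by name only; lists without them were tested as an alternative, chosen after seeing the data. The named genes of each comparison are, among called genes whose libraries did not overlap between the groups and whose mean in the higher group was at least the 25th percentile of genes, 86.8 FPKM: the 8 largest rises and falls with an informative product name, the 2 largest of each among other genes, up to 4 members of each described list, and all alkane 1-monooxygenases, rubredoxins and cytochromes P450 whatever their result. Other genes, such as those at the ends of runs of neighbours, were named after their values were seen.

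The fit was tested on simulated data for each comparison, with 200 of 3348 genes changed by log2 1.5 to 4. The noise was normal, independent between genes and drawn at the spread the same fit had estimated. The test therefore does not cover correlated genes or outlying libraries. For octacosane against glucose, 96% to 100% of changed genes were recovered per fold size, with 3 false calls among 198. For hexadecane against glucose this was 88% to 98%, with 5 false calls among 194, and for octacosane against hexadecane 96% to 100%, with 2 among 199. Alternatives were quantile normalization, no trend, a pseudocount of 0.1, a filter at 10 FPKM, a replicate block, a fit of only the 2 groups compared, no fold minimum and leaving out each library. Only hexadecane kept a replicate 3, so the block also sets that library aside. No comparison had 3 libraries in both groups, so counts from other splits of the samples were not made, and groups of 3 or fewer allow no outlier test. The overlap of both alkanes' calls was set beside 100 simulated data sets without effects that share the glucose libraries. Few genes are called in such data, so they do not give the overlap expected between lists of the sizes found.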

Results

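Dietzia sp. DQ12-45-1b is an actinobacterium that can use n-alkanes, straight-chain hydrocarbons, as its carbon source. RNA was sequenced from cultures in mid-log phase on octacosane (an n-alkane of 28 carbons, at 0.1% mass per volume), hexadecane (an n-alkane of 16 carbons, at 0.1% volume per volume) or glucose (0.2% mass per volume, the control). Per the design text, the pairwise comparisons were made to find how the breakdown of octacosane and hexadecane differ. Each of 9 deposited files gave an FPKM value for 3348 genes, identified by locus tag and product name. The files of octacosane replicates 1 and 3 held identical values and were counted as 1 sample. The file titled glucose replicate 3 carried an octacosane sample name inside, so its group was in doubt and it entered no main comparison. The comparisons therefore rest on 2 octacosane, 3 hexadecane and 2 glucose libraries, and values below are mean FPKM ± SD with those n. Read depth is unknown for these files. The FPKM values of a library summed to between 1.27e+06 and 4.89e+06, which reflects gene composition and not depth.

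The octacosane libraries stood apart from the others in composition. A hypothetical protein, GJR88_RS00580, singled out after its values were seen, took 59.9% and 53.7% of the summed FPKM in the octacosane libraries and 2.62% to 5.42% in the hexadecane and glucose libraries. Its mean was 2.35e+06 ± 8.2e+05 FPKM with octacosane and 43993 ± 15130.0 FPKM with glucose, a log2 fold change of 5.74 (SE 0.63, adjusted p = 0.000497). The octacosane libraries also had 4 and 13 genes under 10 FPKM, against 31 to 61 in the others. The first principal component held 58% of the variance and placed the octacosane libraries on one side and both other groups on the other.

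**Figure D1:**
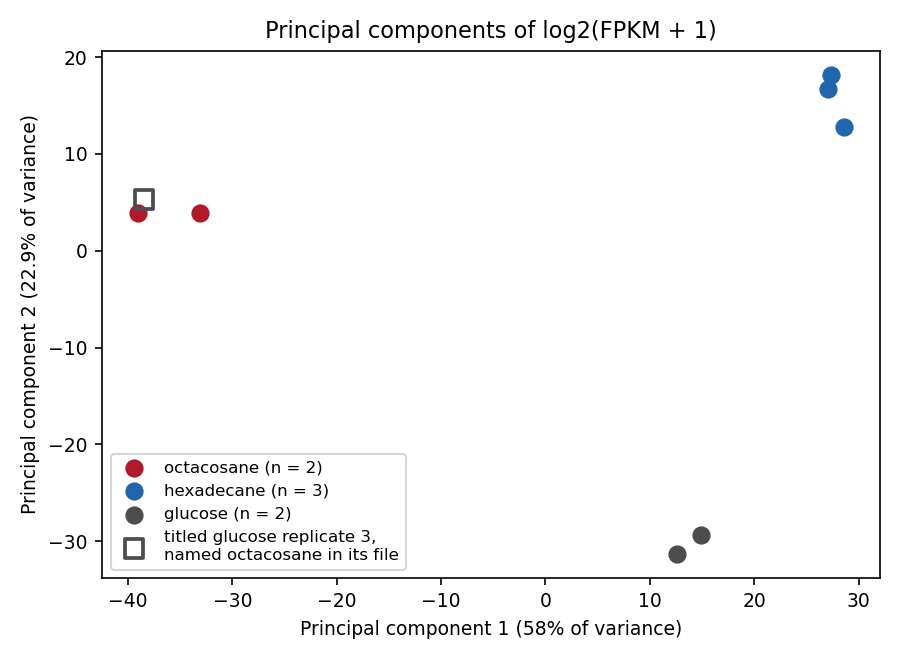
Principal components 1 (58% of variance) and 2 (22.9% of variance) of log2(FPKM + 1), with 1 point per distinct library, coloured by the group in its title. The file titled glucose replicate 3 lies at -38.46 on the first component, beside the octacosane libraries at -39.06 and -33.05, and away from the glucose libraries at 12.58 and 14.92.

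With octacosane, compared with glucose, 5 of 16 alkane oxidation genes, all 3 Suf genes of iron-sulfur cluster assembly and 54 of 211 regulators were higher. A run of 11 genes around the polyketide synthase GJR88_RS05185 and 8 of 26 iron acquisition genes were lower. The gene GJR88_RS00095, named in the files as a FLAG-tagged alkane hydroxylase-rubredoxin, of the enzyme class that places the first oxygen on an alkane, rose from 66.4 ± 0.196 to 938 ± 109.5 FPKM (log2 fold change 3.79, SE 0.40, adjusted p = 0.000382). The separate alkane 1-monooxygenase GJR88_RS01530 rose from 29.4 ± 1.32 to 236 ± 11.5 FPKM (2.96, SE 0.49, adjusted p = 0.00292). Of the cytochromes P450, heme monooxygenases of which some hydroxylate alkanes, GJR88_RS12710 rose from 21.7 ± 0.746 to 159 ± 6.86 FPKM (2.82, adjusted p = 0.000187), and GJR88_RS03330 by 1.46 and GJR88_RS01850 by 1.09 on the log2 scale. The call of GJR88_RS01850 was lost without octacosane replicate 1 (log2 fold change 0.82, adjusted p = 0.0881) and without glucose replicate 1 (0.95, adjusted p = 0.0827). For GJR88_RS17725, a further P450, the change was 0.84 with a 95% interval of -0.26 to 1.95, which did not pass. In all, 5 of the 16 alkane oxidation genes were higher, none was lower and 11 did not pass. The list as a whole did not pass (camera adjusted p = 0.0741), but did without the AlkB dioxygenase GJR88_RS15115, which matches by name only (adjusted p = 0.0493). For the whole list, the camera adjusted p was 0.901 with an estimated correlation and 0.149 after quantile normalization.

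Among genes with an informative product name, the largest rise was that of GJR88_RS03055, a Glu/Leu/Phe/Val dehydrogenase, an enzyme type that removes amino groups from amino acids. It went from 67.3 ± 3.52 to 7008 ± 2715 FPKM (log2 fold change 6.63, SE 0.34, adjusted p = 2.3e-05). Next came a transcriptional repressor, GJR88_RS02315 (4.51), a regulator beside the iron-sulfur cluster genes, GJR88_RS08225 (4.28), a cobyrinic acid a,c-diamide synthase of cobalamin synthesis, GJR88_RS17650 (4.23), and a thioredoxin family protein, GJR88_RS15090 (4.15). The heat shock chaperone gene GJR88_RS06810, of the Hsp20 family, rose by 4.02, while a second Hsp20 gene, GJR88_RS10895, fell (-3.22) and a neighbouring universal stress protein gene, GJR88_RS10900, fell (-2.53). The hypothetical proteins GJR88_RS01645 and GJR88_RS05105 rose by 6.67 and 6.12, the former reaching 33338 ± 14170.0 FPKM. All 3 genes named for the Suf system, which assembles iron-sulfur clusters, rose, with a median log2 fold change of 2.83. This set, like the other sets taken from product names alone, was chosen after the values were seen.

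Several of the largest falls lay in 1 run of neighbours. The 11 neighbouring genes from GJR88_RS05155 to GJR88_RS05205 all fell with octacosane, by log2 fold changes from -6.01 to -1.10. They include a type I polyketide synthase, GJR88_RS05185, which went from 874 ± 242 to 12.3 ± 0.430 FPKM (SE 0.28, adjusted p = 1.53e-05), a nonribosomal peptide synthetase, GJR88_RS05180 (-3.92), a methyltransferase, GJR88_RS05190 (-5.01), an oxidoreductase, GJR88_RS05175 (-4.38), and 2 ABC transporter subunits, GJR88_RS05195 (-5.75) and GJR88_RS05200 (-5.68). A second run of 12 genes, GJR88_RS06690 to GJR88_RS06745, fell with log2 fold changes from -3.44 to -1.06. It holds the siderophore-interacting protein GJR88_RS06735 (-3.44) and the iron ABC transporter permease GJR88_RS06725 (-3.31); siderophores are secreted iron chelators. The metal ABC transporter permease GJR88_RS16285 fell (-5.45), the hypothetical protein GJR88_RS16270 in the same run of neighbours (-5.73), and the holo-ACP synthase GJR88_RS05115 (-3.97). Of the 26 genes of the iron acquisition list, 8 fell (5 without octacosane replicate 1), 2 rose and 16 did not pass (camera adjusted p = 0.19). One of the 2 that rose, GJR88_RS16150, is named a diiron oxygenase (3.42) and entered the list by its name, not as an uptake gene.

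The camera test passed 6 lists between octacosane and glucose at a preset correlation, and none with an estimated correlation. Of 53 ribosomal proteins, 12 fell, only 2 without octacosane replicate 2, and 41 did not pass (camera adjusted p = 0.00199; adjusted p = 0.901 with an estimated correlation). Among them, the gene of 50S protein L10, GJR88_RS12240, went from 3996 ± 286 to 1019 ± 409.7 FPKM (-2.03), a call lost without octacosane replicate 2 (-1.61, adjusted p = 0.0563), and the gene of L16, GJR88_RS11890, fell (-1.41). Of 18 tricarboxylic acid cycle genes, 4 fell, 2 after quantile normalization (camera adjusted p = 0.0072; adjusted p = 0.901 with an estimated correlation), among them an oxoglutarate dehydrogenase E2 component, GJR88_RS06220 (-1.29). Of 22 glycolysis and pentose phosphate genes, 5 fell (camera adjusted p = 0.0159; adjusted p = 0.901 with an estimated correlation). These include phosphofructokinase, GJR88_RS16255 (-1.67), and glucose-6-phosphate dehydrogenase, GJR88_RS08275 (-1.48). Of 16 mycolate and cell wall genes, 6 fell, 3 without glucose replicate 1 (camera adjusted p = 0.0178; adjusted p = 0.901 with an estimated correlation). Besides the polyketide synthases GJR88_RS05185 and GJR88_RS05110 (-3.03), whose product names do not say what they make, they include a mycolyltransferase, GJR88_RS13945, which attaches mycolic acids to the cell wall (-1.66).

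Transcription regulators moved the other way: 54 of 211 rose and 10 fell, the latter 6 without octacosane replicate 2 (camera adjusted p = 0.00199; adjusted p = 0.901 with an estimated correlation). An Lrp/AsnC family regulator, GJR88_RS11445, went from 154 ± 23.4 to 1688 ± 104 FPKM (3.45), an ArsR family regulator, GJR88_RS14395, rose by 3.57, and the regulator GJR88_RS11570 by 3.88. Of 8 pilus and surface genes, 4 rose, 2 without glucose replicate 1 (camera adjusted p = 0.0131; adjusted p = 0.901 with an estimated correlation), a list call that ended under quantile normalization (2 genes, adjusted p = 0.106). They are a Flp family pilin, GJR88_RS14695 (1.26), GJR88_RS14700 (1.57), GJR88_RS14710 (1.45) and a TadA family ATPase, GJR88_RS02525 (1.08), named after their values were seen. Their means with octacosane were 68.2, 32.4, 22.5 and 33.4 FPKM, where the 10 lowest genes of these libraries averaged 9.27 FPKM. Outside the lists that passed, 17 of 101 beta-oxidation genes rose and 5 fell, 10 and 3 without octacosane replicate 1 (camera adjusted p = 0.0633). The rises were led by enoyl-CoA hydratase GJR88_RS13475 (2.96) and acyl-CoA synthetase GJR88_RS03095 (2.80). Of 20 flavin-dependent monooxygenase family genes, a group that includes long-chain alkane monooxygenases in other bacteria, 6 rose and 1 fell (camera adjusted p = 0.118). Of 28 alcohol and aldehyde dehydrogenases, 5 rose, among them GJR88_RS16245 (2.11) and GJR88_RS11965 (2.06). Another of the 5, GJR88_RS01125 (3.01, adjusted p = 0.0498), lost its call without octacosane replicate 2 (1.39, adjusted p = 0.0614) and without either glucose library. All 8 ATP synthase subunit genes fell, with a median log2 fold change of -1.48, 7 of them after quantile normalization and 3 without glucose replicate 1. Malate synthase G, GJR88_RS08805, of the glyoxylate bypass that spares carbon during growth on acetyl-CoA, rose from 289.5 ± 11.8 to 867 ± 198 FPKM (1.56). The other enzyme of the bypass, isocitrate lyase, GJR88_RS13895, did not reach the fold minimum with octacosane.

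Over all genes, limma called 388 genes higher and 344 lower with octacosane than with glucose, at an adjusted p under 0.05 and a change of at least 1 on the log2(FPKM + 1) scale. Counts adjusted over the list alone matched those given here, except for respiration (10 lower instead of 9) and ABC transporters (31 lower instead of 29, with 17 higher in each). With the file titled glucose replicate 3 counted as glucose, limma called 0 genes higher and 0 lower, while 204 were higher and 140 lower at an unadjusted p under 0.05. Counted as octacosane, the name inside the file, it gave 402 higher and 364 lower.

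With hexadecane, compared with glucose, the alkane 1-monooxygenase, the fusion gene and 1 cytochrome P450 rose, and 11 of 13 genes of respiratory complex I and 13 of 17 MCE proteins fell. The alkane 1-monooxygenase GJR88_RS01530 went from 29.4 ± 1.32 to 1574 ± 1059 FPKM (log2 fold change 5.49, SE 0.45, adjusted p = 0.000202). The ferredoxin gene next to it, GJR88_RS01535, a small electron carrier, went from 91.2 ± 29.3 to 13746 ± 9684 FPKM (7.03, SE 0.54, adjusted p = 0.000162). The alkane hydroxylase-rubredoxin fusion GJR88_RS00095 rose to 1887 ± 929 FPKM (4.69, SE 0.36). Cytochrome P450 GJR88_RS17725 went from 269 ± 52.9 to 6260.0 ± 3581 FPKM (4.39, SE 0.44, adjusted p = 0.000473), with its neighbouring ferredoxin GJR88_RS17720 (4.82).

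The alkane 1-monooxygenase and the P450 each lie in a run of neighbours that rose together: 5 genes from GJR88_RS01525 to GJR88_RS01545, by 1.36 to 7.03, and 5 from GJR88_RS17720 to GJR88_RS17740, by 2.32 to 4.82. The first run holds a maleylpyruvate isomerase family protein, GJR88_RS01540 (4.56), and the second a TetR family regulator, GJR88_RS17740 (2.32). An amino acid transporter, GJR88_RS11110, went from 24.9 ± 5.36 to 1106 ± 27.5 FPKM (5.43), and an acyl-CoA dehydrogenase, GJR88_RS14575, which catalyses the first step of beta-oxidation, rose from 156 ± 19.6 to 2566 ± 692 FPKM. Both enzymes of the glyoxylate bypass rose, malate synthase G, GJR88_RS08805, by 2.81 to 2034 ± 138 FPKM and isocitrate lyase, GJR88_RS13895, by 1.95. The latter call was lost without glucose replicate 1 (1.88, adjusted p = 0.059). An IclR family regulator beside malate synthase, GJR88_RS08810, rose by 2.54. The hypothetical proteins GJR88_RS16195 and GJR88_RS03880 rose by 3.24 and 2.96. Of the 16 alkane oxidation genes, 3 rose and 13 did not pass, and the list did not stand apart (camera adjusted p = 0.295); the P450 GJR88_RS12710 changed by 0.82 (95% interval 0.30 to 1.35) and did not reach the fold minimum.

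Complex I, the NADH-quinone oxidoreductase that feeds electrons into the respiratory chain, fell with hexadecane. The 10 neighbouring genes from GJR88_RS01740 to GJR88_RS01785 fell by log2 fold changes from -3.76 to -2.75, and 11 of the 13 genes with this product name passed. Subunit L, GJR88_RS01745, went from 263 ± 128 to 19.1 ± 10.3 FPKM (SE 0.44, adjusted p = 0.000992), subunit G, GJR88_RS01770, fell (-3.51), as did NuoH, GJR88_RS01765 (-3.48), and NuoI, GJR88_RS01760 (-3.42). The respiration and ATP synthase list had 11 of 32 members lower and 2 higher (camera adjusted p = 1.93e-05; adjusted p = 0.901 with an estimated correlation). One that rose, GJR88_RS04110 (1.66), is a tRNA modification ATPase and not respiratory by name; the other, GJR88_RS03695 (1.16), is a subunit of cytochrome d ubiquinol oxidase. Of 17 MCE family proteins, parts of lipid uptake systems in actinobacteria, 13 fell, among them GJR88_RS12190 (-3.55), GJR88_RS12200 (-3.49) and GJR88_RS12215 (-3.48). The cation acetate symporter GJR88_RS04050 went from 1314 ± 440.1 to 66.8 ± 23.6 FPKM (-4.29, SE 0.32, adjusted p = 0.000162), and the hypothetical proteins GJR88_RS01180 and GJR88_RS09820 fell (-3.62 and -2.95).

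Among the other lists, iron acquisition had 9 of 26 members higher, 5 without glucose replicate 1, and none lower (camera adjusted p = 0.0706). A run of 9 genes from GJR88_RS03845 to GJR88_RS03885 holds 4 of them, the hemin receptor GJR88_RS03855 (2.64), the permease GJR88_RS03860 (2.45), the heme ABC transporter ATPase GJR88_RS03865 (2.61) and a heme oxygenase, GJR88_RS03885 (1.22). Another, the diiron oxygenase GJR88_RS16150, entered the list by its name, not as an uptake gene. Without members that match by name only, 8 of 23 were higher (camera adjusted p = 0.0823). Ribosomal proteins stood lower than other genes as a list (camera adjusted p = 0.00645, and 0.901 with an estimated correlation). That list call was lost with a replicate block (0.0535) and with the file titled glucose replicate 3 as glucose (0.698). By limma 0 of the 53 were called, but 9 were lower after quantile normalization, and their median in the main fit was -0.22. Of 16 fatty acid synthesis genes, 2 fell, 1 without glucose replicate 1, and 1 rose (camera adjusted p = 0.021; adjusted p = 0.901 with an estimated correlation); the acyl-CoA carboxylase beta subunit GJR88_RS01465 fell (-1.24). Without 6 members that act on other substrates by name this list no longer passed (adjusted p = 0.13). Of 101 beta-oxidation genes 11 rose, 6 without glucose replicate 1, and 14 fell (camera adjusted p = 0.346), with a median and mean above 0 and a test direction below other genes. The alcohol and aldehyde dehydrogenase list had the same signs, and 2 of its 28 members rose and 4 fell, the largest rise being a succinate-semialdehyde dehydrogenase, GJR88_RS01245 (2.85), which does not act on fatty aldehydes by name.

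In total, limma called 285 genes higher and 173 lower with hexadecane than with glucose, and the median gene changed by 0.21. After quantile normalization the median was 0.05 and the split turned to 161 higher and 240 lower, so the balance of rises and falls rests on the authors' scaling. Leaving out glucose replicate 1 gave 144 higher and 115 lower, and leaving out hexadecane replicate 3 gave 189 higher and 130 lower. With the file titled glucose replicate 3 counted as glucose, the counts were 147 higher and 96 lower. Counts adjusted over the list alone were the same as those given.

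**Figure D2:**
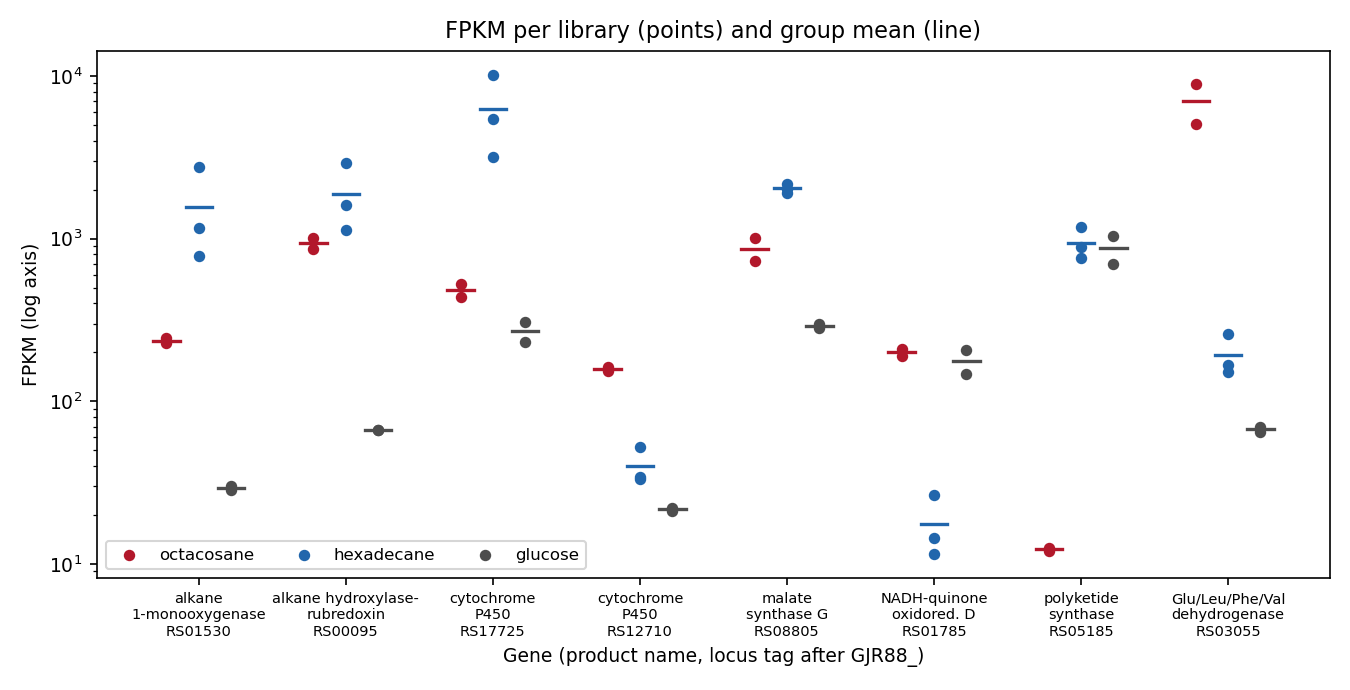
FPKM on a log axis for 8 genes, with 1 point per library (octacosane n = 2, hexadecane n = 3, glucose n = 2) and a line at each group mean. The alkane 1-monooxygenase GJR88_RS01530 lies at 29.4 FPKM with glucose, 236 with octacosane and 1574 with hexadecane, while the complex I subunit D, GJR88_RS01785, lies lowest with hexadecane at 17.5 FPKM.

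The alkanes differ in chain length, 28 against 16 carbons, and were compared with each other directly; both were given at 0.1%, but by mass for octacosane and by volume for hexadecane. The alkane 1-monooxygenase GJR88_RS01530 was lower with octacosane than with hexadecane (log2 fold change -2.52, SE 0.45, adjusted p = 0.00286), as were its ferredoxin GJR88_RS01535 (-4.09) and the P450 GJR88_RS17725 (-3.54, adjusted p = 0.000568). Other P450 genes were higher with octacosane: GJR88_RS12710 by 1.99 (adjusted p = 0.000411), GJR88_RS17080 by 1.39 and GJR88_RS01850 by 1.32. For the fusion gene GJR88_RS00095 the difference was -0.90, with a 95% interval of -1.73 to -0.07 and an adjusted p of 0.0763, so it did not pass. Without hexadecane replicate 2 it did (-1.22, adjusted p = 0.016). The remaining P450 genes did not pass either, with intervals such as -0.53 to 0.30 for GJR88_RS01670 and 0.06 to 1.29 for GJR88_RS03330; without octacosane replicate 2 the latter passed (1.05, adjusted p = 0.0276).

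Many iron acquisition genes were lower with octacosane than with hexadecane. Of the 26 iron acquisition genes, 15 were lower, 1 was higher and 10 did not pass (camera adjusted p = 0.019; adjusted p = 0.901 with an estimated correlation). The siderophore-interacting protein gene GJR88_RS06735 stood at 186 ± 88.5 FPKM with octacosane and 2719.5 ± 829 with hexadecane (-3.90, SE 0.38, adjusted p = 0.000162). The peptide synthetase GJR88_RS05180 (-3.75), the heme ABC transporter ATPase GJR88_RS03865 (-3.44) and the iron ABC permease GJR88_RS06720 (-3.33) were lower too. The synthetase entered the list by its product name, which does not say what it makes. Among metal ABC transporter permeases, GJR88_RS16285 differed by -5.50 and GJR88_RS04265 by -4.13. The polyketide synthase GJR88_RS05185 had the lowest log2 fold change of the informative names, -6.13 (SE 0.26). A GTP-binding protein, GJR88_RS14310 (-5.50), and a copper chaperone, GJR88_RS14635 (-4.80), were also lower. The octacosane libraries in this comparison are those in which GJR88_RS00580 took over 53% of the summed FPKM.

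Higher with octacosane than with hexadecane were the Glu/Leu/Phe/Val dehydrogenase GJR88_RS03055 (5.17, SE 0.31, adjusted p = 1.72e-05), complex I and parts of fatty acid breakdown. Of the 13 NADH-quinone oxidoreductase genes 12 were higher, led by subunit A, GJR88_RS01800, at 2719 ± 1106 against 121 ± 50.6 FPKM (4.49). Against glucose, octacosane raised 2 of the 13 and lowered 1. All 3 Suf genes were higher. Of 101 beta-oxidation genes, 19 were higher and 11 lower (camera adjusted p = 0.0178; adjusted p = 0.901 with an estimated correlation), a list call that ended under quantile normalization (adjusted p = 0.158). The fatty acid-CoA ligases GJR88_RS00750 (3.46) and GJR88_RS01080 (3.02), the acyl-CoA dehydrogenase GJR88_RS13365 (3.14) and the crotonase GJR88_RS13375 (4.29) were higher, whereas the acyl-CoA dehydrogenase GJR88_RS14575 was lower (-3.62). An aldehyde dehydrogenase, GJR88_RS01125, averaged 3273 ± 3747 FPKM with octacosane (4.44, adjusted p = 0.00649), with an SD above its mean; without hexadecane replicate 2 the call was lost (4.31, adjusted p = 0.0517). A murein L,D-transpeptidase, GJR88_RS02870 (4.23), a ferredoxin, GJR88_RS03425 (4.14), a fasciclin domain protein, GJR88_RS15980 (4.16), and the hypothetical proteins GJR88_RS01645 (8.01) and GJR88_RS05105 (6.12) were higher as well. Both glyoxylate bypass genes were lower, malate synthase G, GJR88_RS08805 (-1.25), and isocitrate lyase, GJR88_RS13895 (-1.37), the latter not without octacosane replicate 2 (-1.16, adjusted p = 0.097).

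Of 211 regulators, 35 were higher and 24 lower, the latter 15 after quantile normalization, with octacosane than with hexadecane (camera adjusted p = 0.0323, and 0.901 with an estimated correlation). Higher ones include GJR88_RS01085 (4.31) and GJR88_RS12615 (3.85). The list call was lost with a replicate block (camera adjusted p = 0.0535) and with the file titled glucose replicate 3 as glucose (0.0991). Of 8 pilus genes, 3 were higher (camera adjusted p = 0.0235; adjusted p = 0.901 with an estimated correlation), namely GJR88_RS14695 (1.45), GJR88_RS14710 (1.51) and GJR88_RS02525 (1.41); this list call ended under quantile normalization (adjusted p = 0.202). Over all genes, limma called 347 higher and 538 lower with octacosane, and the median gene differed by -0.24. After quantile normalization the median was -0.05 and the split was 390 higher and 347 lower, so here too the balance rests on the scaling. With the file titled glucose replicate 3 counted as glucose the counts were 180 higher and 378 lower. Adjusted over the list alone, the iron list had 2 higher instead of 1, the alcohol and aldehyde dehydrogenase list 8 higher instead of 7, ribosomal proteins 3 lower instead of 4 and chaperones 9 lower instead of 8.

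**Figure D3:**
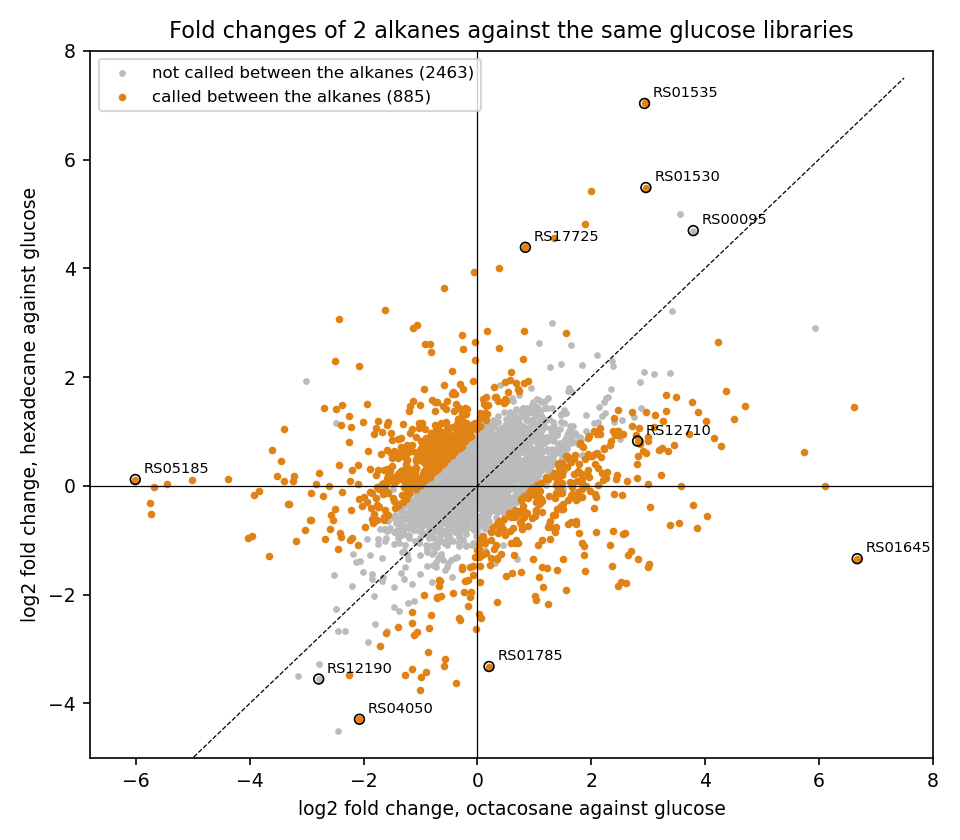
Log2 fold change of each of 3348 genes with octacosane (horizontal) and hexadecane (vertical), both against the same 2 glucose libraries; orange points passed the test between the alkanes and the dashed line marks equal change. GJR88_RS01530 and GJR88_RS17725 lie above the line, and GJR88_RS05185 lies far to the left at -6.01.

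Both alkanes raised 94 of the same genes and lowered 53 of the same genes relative to glucose. After quantile normalization these counts were 62 and 89, which turns their balance, and without glucose replicate 1 they were 43 and 39. Independent lists of these sizes would share 33.03 and 17.78. Simulated groups without any effect against the same glucose libraries shared at most 1 in each direction. Few genes are called without effects, so that count cannot show how much of the overlap comes from the shared libraries. Because both comparisons use the same 2 glucose libraries, part of the excess may come from them. The log2 fold changes correlated across genes at r = 0.31. Simulated unchanged groups had a mean r of 0.552, which the shared glucose libraries set in data that hold only noise. The observed r cannot be compared with it, because the real data also hold effects. The covariance was 0.267 against a simulated 0.0595, a difference of 0.207. Genes are not independent replicates. Raised by both were the alkane 1-monooxygenase GJR88_RS01530, the fusion gene GJR88_RS00095, the malate synthase GJR88_RS08805 and the diiron oxygenase GJR88_RS16150 (3.42 with octacosane and 3.22 with hexadecane). MCE proteins were lowered by each alkane, 11 of 17 by octacosane and 13 by hexadecane, most of them in 2 runs of neighbours, and the same counts were found after quantile normalization. A mycolyltransferase, GJR88_RS13945 (-1.66 and -1.68), and a propionyl-CoA carboxylase beta subunit, GJR88_RS06015 (-2.14 and -1.40), fell with both.

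**Figure D4:**
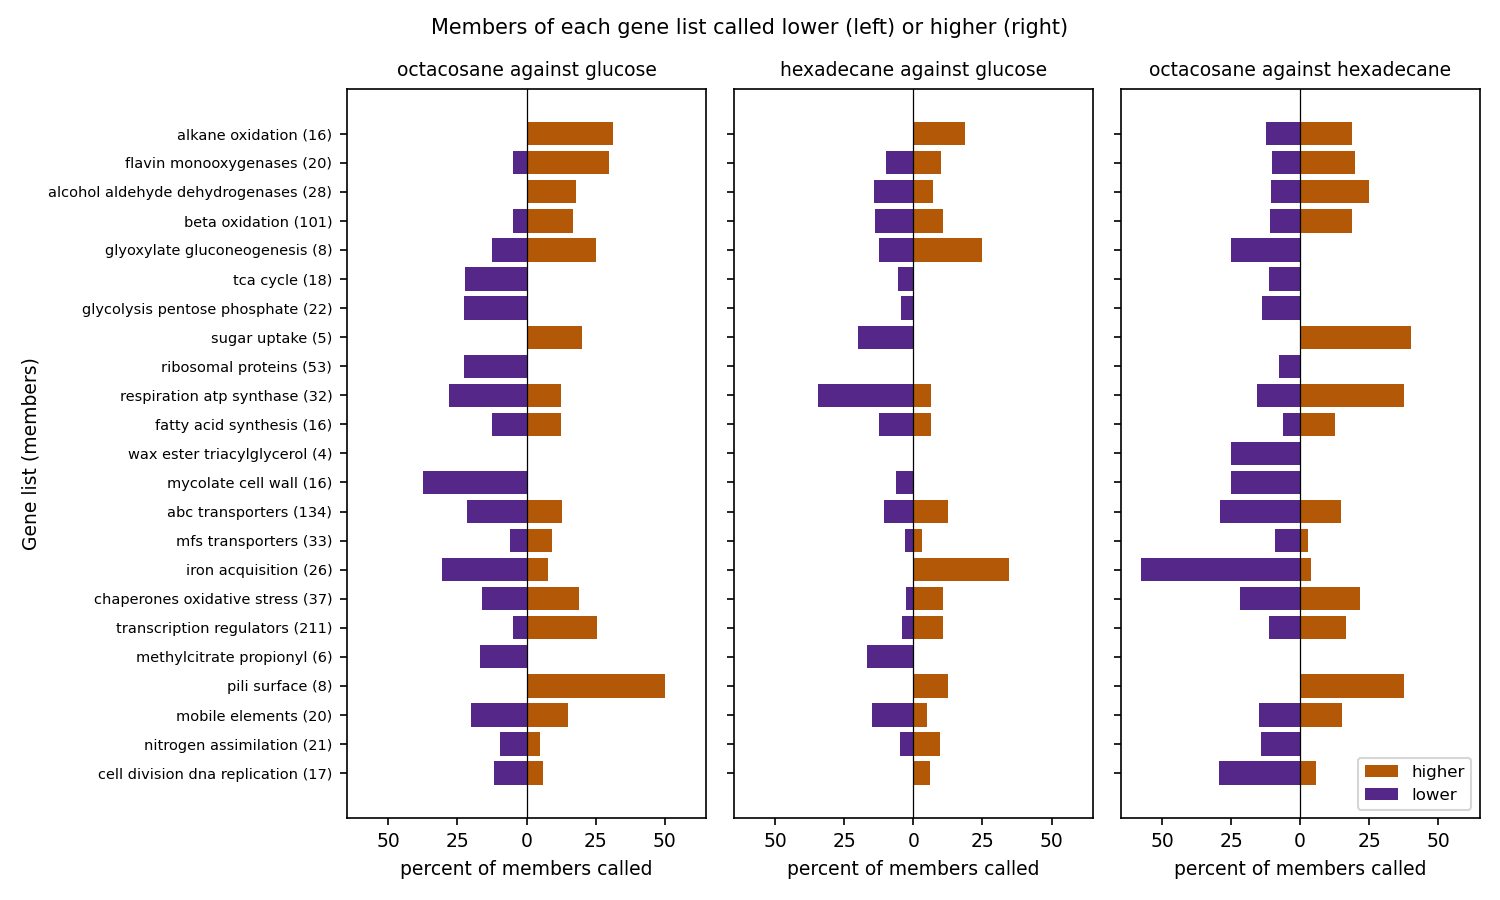
Percent of the members of each of 23 gene lists, with the number of members in brackets, that were called lower (left) or higher (right) in each comparison. Iron acquisition has 15 of 26 members lower with octacosane than with hexadecane, and respiration has 11 of 32 lower with hexadecane than with glucose.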

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

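The tests of the file titled glucose replicate 3, of separate handling and of library scale for low genes were chosen after the results were seen.

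The file titled glucose replicate 3, which carries an octacosane sample name inside and was left out of the main comparisons, held an octacosane-like signal: at 728 of the 732 genes called between octacosane and glucose in the other libraries (99.5%) its value lay nearer the octacosane mean. A copy of another octacosane file is argued against, since at most 3 of 3348 genes had the same FPKM. A mixture of glucose and octacosane RNA is argued against too: at 24 genes at least 8 times lower with octacosane, the file lay a median of -0.15% of the way from the octacosane to the glucose mean. An octacosane library under a glucose title remains a candidate explanation. The name inside is that of octacosane replicate 2, which no other file carries. GJR88_RS00580 took 55.9% of its summed FPKM, against 59.9% and 53.7% in the octacosane libraries and 4.04% and 2.62% in the other glucose libraries. A glucose culture with an octacosane-type transcriptome was not tested and is not excluded by these values.

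The alkanes changed 37 genes in opposite directions against glucose, a difference between groups. Each was also called between the alkanes. This is no separate evidence, because that fold change is the difference of the other 2 in the same model. Of these, 19 were higher with octacosane and lower with hexadecane, among them the acyl-CoA dehydrogenase GJR88_RS13365 (1.88 and -1.26), the crotonase GJR88_RS13375 (2.53 and -1.76), the fatty acid-CoA ligase GJR88_RS00750 (1.55 and -1.91) and the complex I subunit GJR88_RS01800 (3.00 and -1.48). The other 18 were lower with octacosane and higher with hexadecane, among them the copper chaperone GJR88_RS14635 (-2.50 and 2.30), the Dyp-type peroxidase GJR88_RS14630 (-2.08 and 2.21) and the metal ABC permease GJR88_RS04265 (-2.70 and 1.43).

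Iron acquisition genes were lower with octacosane than with hexadecane, 15 of 26. Library scale, including a few genes taking most of the FPKM, is argued against, since 14 of the 15 stayed past the threshold after quantile normalization. A single deviating octacosane library is argued against as well, since 13 stayed without octacosane replicate 1 and 15 without replicate 2. Separate handling of the octacosane cultures or libraries cannot be told apart from the carbon source, because the main axis, with 58% of the variance, places the octacosane libraries, and the file titled glucose replicate 3, apart from the others and the labels give no batch. A carbon source effect on iron uptake therefore stays a hypothesis.

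The octacosane libraries had few genes at low values. Library scale is argued against: 4 and 9 genes lay under 6% of the library median with octacosane, against 46 to 64 in the others. For uniform background reads, a rule written beforehand took the mean of the 10 lowest genes with octacosane, 9.27 FPKM, as a bound. A median rise above it was to count against background. Of 16 genes under 10 FPKM in all hexadecane libraries, 15 were higher with octacosane than with glucose. The median rise of the 16 was 10.81 FPKM (quartiles 7.72 and 17.64), above the bound and so against background by that rule. The bound, however, averages the 10 lowest genes, so a uniform background could itself give a rise near or above it. The quartiles, which were not part of the rule, lie on both sides of the bound. The rule therefore cannot decide, and background was not excluded for these genes. A biological rise of these genes stays open, so fold changes of genes near this level may be affected.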

How the results depend on the processing

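The fit with the file titled glucose replicate 3 under each of its names, the 10 FPKM filter and the lists without misfits were chosen after seeing the data; the other alternatives were planned. The low-value filter removed no gene, so its absence is no test. Between octacosane and glucose (388 higher, 344 lower) the counts stayed within 1.5 times of these under the alternatives run, except with that file as glucose (0 and 0 by limma); leaving out 1 library gave 311 to 367 and 244 to 303. For hexadecane against glucose (285 and 173), quantile normalization gave 161 higher, the file as glucose 147 and 96, no fold minimum 550 and 267, and leaving out 1 library 144 to 307 and 115 to 236. For octacosane against hexadecane (347 and 538), quantile normalization gave 347 lower, of which 322 were among the 538, the file as glucose 180 higher, no fold minimum 887 lower, and leaving out 1 library 291 to 389 and 422 to 572. Genes raised by both alkanes (94) numbered 62 after quantile normalization, 0 with the file as glucose, 186 without fold minimum and 43 to 72 without 1 glucose library; genes lowered by both (53) numbered 89, 0, 104 and 39 to 51. With 1 library left in a group, that library is assumed to vary like the other groups. Between the alkanes, the file titled glucose replicate 3 enters neither group when counted as glucose. The median fold change stayed at -0.24, and all 180 higher and 378 lower calls were among the main ones. The lost calls there can come only from the estimated spread, which all groups share. Apart from that, fewer libraries and the fold minimum, the cause was not tested. List calls (13 of 66) numbered 0 by camera with an estimated correlation, 11 after quantile normalization (10 of them shared) and 17 without misfits (12 shared). Without misfits, alkane oxidation and respiration (adjusted p = 0.0493 and 0.0158, octacosane against glucose), tricarboxylic acid cycle and methylcitrate genes (0.0325 and 0.03, hexadecane against glucose) and alcohol and aldehyde dehydrogenases (0.0419, between the alkanes) gained a call. Quantile normalization added the tricarboxylic acid cycle (0.00759, hexadecane against glucose), and the file as octacosane added beta-oxidation (0.0477, octacosane against glucose). With that file as glucose there were 11 list calls, 9 of them shared. Ribosomal proteins (0.141 and 0.698, octacosane and hexadecane against glucose), fatty acid synthesis (0.141, hexadecane against glucose) and regulators (0.0991, between the alkanes) lost the call, while iron acquisition (0.0326, hexadecane against glucose) and respiration (0.022, between the alkanes) gained one. The replicate numbers pair only 2 hexadecane and glucose libraries (correlations of deviations 0.618 and 0.605), too few to show pairing, and octacosane numbers are unreliable. A replicate block gave 390 and 346, 220 and 139, and 333 and 535 calls, and 12 list calls, 11 of them shared. Among the libraries compared only hexadecane had a replicate 3, so the block takes that library out of the fold changes. Median fold changes with the block were 0.2293 (hexadecane against glucose) and -0.2435 (octacosane against hexadecane), the same as without hexadecane replicate 3. The block is therefore no test of pairing alone. It ended the list calls of ribosomal proteins between hexadecane and glucose and of regulators between octacosane and hexadecane (adjusted p = 0.0535 each), and it added ribosomal proteins between octacosane and hexadecane (adjusted p = 0.0348). It also ended the call of the aldehyde dehydrogenase GJR88_RS01125 between octacosane and hexadecane (4.28, adjusted p = 0.0745) and against glucose (adjusted p = 0.168); the latter also ended with only the 2 groups compared (0.233) and the 10 FPKM filter (0.0501). Of 259 values of named genes, 227 of them past the threshold, none reversed under any alternative. Most were named because they passed in these data, many with the largest fold changes. A reversal was therefore unlikely, and other called genes are not covered. Of the 259, 19 changed side of the threshold after quantile normalization, 9 with the block, 1 with the 10 FPKM filter and 1 with only the 2 groups compared. With the file as octacosane 4 changed side, and with it as glucose 124. Each of these changes was a lost call. Leaving out 1 library kept 1113 such values on their side, with 87 losing and 3 gaining a call. The unknown depth limits what can be said of genes at low FPKM.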

Other observations

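With octacosane, 4 genes of class Ib ribonucleotide reductase, which makes deoxyribonucleotides, fell against glucose together with 2 neighbours, by -4.04 to -2.09 over GJR88_RS04940 to GJR88_RS04965, and a second NrdH gene elsewhere rose; this family and the runs of neighbours below were picked after their values were seen. Against hexadecane the same 6 genes were lower by -3.07 to -1.69. Of 17 replication and division genes, 5 were lower, 3 after quantile normalization, and 1 higher with octacosane than with hexadecane, and the list did not pass (camera adjusted p = 0.346); the lower ones include DNA polymerase III subunit alpha, GJR88_RS06575 (-1.50). Glutamate synthase subunit beta, GJR88_RS01190, of ammonium assimilation, stood at 243 ± 3.75 FPKM with octacosane, 1021 ± 72.1 with hexadecane and 618 ± 29.9 with glucose. A run of 10 neighbours from GJR88_RS02365 to GJR88_RS02415, which include cation/proton antiporter subunits, was lower with octacosane than with hexadecane by -2.48 to -1.30. With hexadecane, 7 neighbours from GJR88_RS11390 to GJR88_RS11420, which include CoA transferase subunits and an acyl-CoA dehydrogenase, fell against glucose by -2.52 to -1.08.

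The remaining lists gave no call as fixed, though methylcitrate and propionyl-CoA genes passed between hexadecane and glucose without 1 member that matches by name only (camera adjusted p = 0.03). As fixed, that list had a camera adjusted p of 0.0593, and of 0.901 with an estimated correlation. ABC transporters had 39 of 134 members lower and 20 higher, the latter 12 without octacosane replicate 1, with octacosane than with hexadecane (camera adjusted p = 0.994), MFS transporters 3 of 33 lower and 1 higher, chaperones and oxidative stress genes 8 of 37 in each direction (5 lower without octacosane replicate 2), mobile elements 3 of 20 in each direction (0 higher without octacosane replicate 1) and nitrogen genes 3 of 21 lower (1 after quantile normalization). For ABC transporters the median and mean lay below 0 and the test direction above other genes; for chaperones and mobile elements the median lay above 0 and the mean below. Of 5 sugar uptake genes 2 were higher with octacosane than with hexadecane (0 without hexadecane replicate 3), and of 6 methylcitrate and propionyl-CoA genes none passed between octacosane and hexadecane, while 1 fell with each alkane against glucose. The wax ester and triacylglycerol list, with 4 members, was too small to test; 1 synthase, GJR88_RS04630, was lower with octacosane than with hexadecane (-1.11), a call lost after quantile normalization (-0.76) and without octacosane replicate 1 (-0.97).

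Neighbouring genes were often called in the same direction. Between octacosane and hexadecane, 373 of 407 neighbouring pairs of called genes (91.6%) shared a direction, against at most 63.9% in 10000 random gene orders (permutation p = 0.0001, the smallest these orders can give). The longest run had 13 genes, and the longest in 500 random orders had 7. For octacosane and for hexadecane against glucose the shares were 94.5% and 96.0%.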
